A study of Homo sapiens with 8 samples.

How the data were processed

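RNA of the Hodgkin lymphoma lines KM-H2 and L428, each stably carrying KLF4-ER and treated with 4-OHT or ethanol for 24 h, was read on 8 whole-transcript arrays, 2 per line and treatment. Per the labels, 200 ng of total RNA was amplified and labelled for each array and 5.5 µg of single-stranded DNA was hybridised. The authors summarised the probe intensities with the robust multichip average (RMA) in Affymetrix Expression Console, whose version is not stated. The deposited values are on the log2 scale, 1 per probe set and array, between 1.53 and 13.5, and were normalized between the arrays by the authors; they were used as deposited. Arrays give no counts, and their number limits the precision.

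The table held 33297 probe sets. Those with at least 1 gene symbol in the platform's probe table were tested, 21214 in number: 19460 with 1 symbol and 1754 with several, the latter counted and not named. The probe table carries annotation of 2016, and 19429 of the probe sets with 1 symbol were matched by gene identifier to a current gene table, from which symbols were taken; 31 were not matched. The other 12083 probe sets, controls and unnamed ones, were left out of the tests and enter an alternative and a count. A gene with several probe sets, as 769 genes had, was represented by the one with the highest mean over the 8 arrays, which gave 18417 genes. Among genes with several probe sets, 1 had calls in opposite directions in KM-H2 and 0 in L428 by limma. No coordinates were used.

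Group means were fitted with limma (version 3.58.1, R 4.3.3; lmFit and eBayes) over 4 groups, without a replicate block, with 4 residual degrees of freedom and a prior of 6.16, 10.2 in total. The comparisons were 4-OHT against vehicle in KM-H2 and in L428, the mean of these, their difference (L428 minus KM-H2) and L428 against KM-H2 with vehicle. Limma's moderated test was two-sided, and p-values were adjusted by Benjamini-Hochberg over the 21214 probe sets within each comparison; an adjusted p under 0.05 was called. Errors of fold changes are limma's SE, and errors of group means the SD of 2 arrays. The median SD between replicates was 0.083. The overlap of calls between the lines was tested with Fisher's exact test over the probe sets, which are not independent. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

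Before the data were examined, 37 gene lists with 710 genes in all were written from general knowledge for pathways, transcription factor targets and markers of other cell types; 646 of the genes were measured by a probe set of their own, 2 of them through an older symbol. The other 64 were not analysed here, 21 of them because they lay in probe sets of several genes. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 37 lists within each comparison. Beside it stood camera at an estimated correlation, and fry. At an estimated correlation camera also works with only the 4 residual degrees of freedom, and at a preset one with about the number of genes. Its p-values can therefore rise even where members are not correlated. Members were counted both from the adjusted p over all probe sets and adjusted over the list alone. Some genes stand in several lists, such as BAK1 and ODC1. The lists carry no direction for their members. A list of reported targets called upward or downward thus does not show that its members moved as reported. The list called cholesterol synthesis also holds genes outside that pathway, such as FADS2 and SREBF1.

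The genes named were also set by a rule fixed before the data were examined. For each line the rule took the 12 genes of largest rise and the 12 of largest fall among those called with both treated arrays on the same side of both vehicle arrays. For the other comparisons it took 8 each way, and for each list up to 4 called members, or up to 2 of lowest p where none was called. It added 12 genes whatever their values: KLF4, ESR1, BAK1, CDKN1A, CCND2, MYC, TNFRSF8, PRDM1, PAX5, BCL2, MKI67 and HMGCS1.

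Alternatives changed 1 choice at a time. They left out dim probe sets, tested all probe sets, normalized by quantiles once more, centred each array on its median, blocked on the replicate letter, fitted each line alone, used eBayes with trend and robust settings or array weights, asked for a fold change of 2, took the mean of a gene's probe sets, and left out each array in turn. With 1 array left out, the lone array of its group was assumed to vary like the other groups. Cyclic loess was chosen after seeing the data. The methods were tested on simulated data: with changes added to the KM-H2 comparison, limma recovered 2%, 52%, 98% and 100% of genes changed by 0.3, 0.5, 1 and 2 on the log2 scale, with 10 false calls among 136. Camera recovered a list of 20 genes shifted by 0.5 and called 0 of the lists that were not shifted, at the preset correlation. At the estimated correlation it also recovered the shifted list (camera adjusted p = 0.00308). The simulated noise was independent between genes, and no gene outside that list was changed in KM-H2. It therefore does not show how camera performs where members are correlated or many other genes change.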

Results

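Gene expression was measured on 8 Affymetrix Human Gene 1.0 ST arrays in 2 human cell lines of classical Hodgkin lymphoma, KM-H2 and L428, a tumour whose cells descend from B cells. Both lines stably carried a fusion of the transcription factor KLF4 with the oestrogen receptor, KLF4-ER. 4-hydroxytamoxifen (4-OHT) is a ligand of such fusions and is used to bring them into action. Each line received either 4-OHT or its ethanol vehicle for 24 h. The dose is labelled 200 µM, high for a ligand of such fusions, and its unit could not be checked here. The experiment was done 2 times, which gave 4 groups of 2 arrays. The arrays were alike in scale, with medians between 4.38 and 4.51 on the log2 scale. Replicate arrays correlated with Pearson's r of 0.994 to 0.996 across probe sets, arrays of the same line with different treatment with r of up to 0.974, and arrays of different lines with r of 0.909 to 0.927; probe sets are not independent replicates. In a principal component analysis the first 3 components held 69.3%, 19.3% and 6.81% of the variance. The number of arrays limits the precision. Nothing in the labels says that the replicates were separate cultures beyond the experiment having been done 2 times, so the p-values measure the spread between these arrays, some of which may be technical. Cells without the fusion were not given 4-OHT in this series, so actions of 4-OHT of its own and those of the activated fusion were measured together.

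The probe set of KLF4 (8163002) and that of the oestrogen receptor gene ESR1 (8122843) show the level of these transcripts, not the activation of the fusion protein, which was not measured; the labels give the cells of all 4 groups as stably transfected with the fusion gene. KLF4 stood at 6.73 with vehicle and 6.69 with 4-OHT in KM-H2 (log2 fold change −0.05 ± 0.09 SE, adjusted p = 0.822) and at 6.67 and 6.65 in L428 (−0.02 ± 0.09, adjusted p = 0.902). ESR1 stood at 3.71 and 3.77 in KM-H2 (adjusted p = 0.803) and at 3.74 and 3.77 in L428 (adjusted p = 0.835). Neither transcript passed the test in either line.

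The first comparison asked which transcripts differed between 4-OHT and vehicle in KM-H2 cells carrying KLF4-ER. BAK1, which encodes a pore-forming, death-promoting protein of the BCL2 family, rose 8.41-fold, from 6.51 ± 0.09 to 9.58 ± 0.10 on the log2 scale (mean ± SD, n = 2 arrays per group; adjusted p = 1.95e-07). The chemokine gene CCL5 fell 18.7-fold, from 10.05 to 5.83 (log2 fold change −4.23 ± 0.13 SE), and the proto-oncogene MYC fell 2.44-fold, from 7.17 to 5.88. NF-κB target genes, MHC class II genes, genes of ribosome biogenesis and genes of DNA replication fell as groups by camera at its preset correlation, while genes of lysosomes and autophagy rose. None of these list calls held with an estimated correlation, where the adjusted p was 0.674 for the replication genes and 0.355 for each of the others. Of the 21214 probe sets tested, 5068 passed an adjusted p of 0.05, 2431 upward and 2637 downward, and 656 of the rises and 437 of the falls were at least 2-fold. These changed probe sets stood for 2204 genes that rose and 2261 that fell. Which direction held the larger number was not stable: rises outnumbered falls when each array was centred on its median (2750 against 2262), with cyclic loess (2540 against 2461), without KM-H2 control A (1877 against 1775) and without KM-H2 4-OHT B (2348 against 2142).

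CD52, which encodes a small lymphocyte surface glycoprotein, had the largest rise in KM-H2, 19.2-fold (log2 fold change 4.26 ± 0.19 SE). The integrin gene ITGB7 rose 13.0-fold, the Eph receptor gene EPHB6 13.0-fold and the tetraspanin gene CD9 11.2-fold, from 7.67 to 11.15. SUSD2 rose 13.3-fold, ATP1B1, a subunit of the sodium pump, 10.5-fold, the calcium-binding S100A16 10.3-fold and the metalloproteinase gene ADAM15 9.13-fold. ATL1 rose 11.3-fold and GPR155 9.73-fold. AHNAK2 rose 10.6-fold with the widest error among these genes (log2 fold change 3.41 ± 0.36), from a vehicle level of 3.22 that lay among the dimmest probe sets, so its fold is a rough size. Among the strongest falls were, after CCL5, NIPSNAP2 (13.8-fold), the interferon-inducible chemokine gene CXCL10 (12.2-fold), the cytokine gene LTA (8.31-fold), the chemokine gene CXCL12 (7.88-fold), RASGEF1B (7.37-fold), the kinase gene PIM2 (7.22-fold), the homeobox gene PRRX1 (7.10-fold) and COQ8A (6.72-fold). HLA-DPB1, a chain of an antigen-presenting MHC class II molecule, fell 6.61-fold, the TNF receptor family gene TNFRSF9 6.44-fold and the signalling regulator RGS1 6.18-fold. The SE of the log2 fold changes of these genes lay between 0.11 and 0.36. In each of them both treated arrays lay on the same side of both vehicle arrays, as the rule for naming required. Genes with close relatives, among them HLA-DPB1, may share probes with those relatives, which the table does not allow to be checked.

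Of 29 measured NF-κB target genes, 20 fell and 3 rose in KM-H2, and 6 did not pass the test (20 and 4 adjusted over the list alone). The examples with the largest changes were CCL5, CXCL10, LTA and CD40, a B-cell co-stimulatory receptor that fell 4.15-fold. The list's median log2 fold change was −0.82 (camera adjusted p = 1.39e-08; adjusted p = 0.355 with an estimated correlation). Of 9 measured MHC class II genes, 7 fell and 2 did not pass (7 adjusted over the list alone): HLA-DPB1 fell 6.61-fold, HLA-DMB 4.32-fold, HLA-DMA 3.72-fold and HLA-DPA1 3.45-fold. The list's median was −1.26 (camera adjusted p = 2.68e-07; adjusted p = 0.355 with an estimated correlation).

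Of 22 measured genes of ribosome biogenesis and MYC targets, 19 fell and 1 rose in KM-H2, and 2 did not pass (19 and 1 adjusted over the list alone). CAD, which begins pyrimidine synthesis, fell 2.61-fold, the nucleolar gene NPM1 2.05-fold and RRP9 1.94-fold. The exception was ODC1, the first enzyme of polyamine synthesis, which rose 1.63-fold; it was picked out after its values were seen, although the rule names it. The list's median was −0.62 (camera adjusted p = 4.33e-09; adjusted p = 0.355 with an estimated correlation). Of 35 genes of the G1/S transition and replication, 15 fell, 2 rose and 18 did not pass (18 and 2 adjusted over the list alone). TYMS, the thymidylate synthase gene, fell from 10.43 to 9.44 on the log2 scale, the cyclin gene CCNE2 1.90-fold and the replicative helicase gene MCM2 1.68-fold, and TK1, the thymidine kinase gene, rose 2.51-fold. The list's median was −0.26 (camera adjusted p = 0.0014; adjusted p = 0.674 with an estimated correlation). Of 35 genes of mitosis, 14 rose, 5 fell and 16 did not pass (15 and 6 adjusted over the list alone), with ANLN up 2.22-fold and PRC1 up 2.02-fold. As a list they did not pass (camera adjusted p = 0.0508), but did with the replicate letter as a block across both lines (0.044) and without KM-H2 control A (0.0348), over a range of 0.0348 to 0.214 in all alternatives at the preset correlation. By fry the list was called upward (0.0039). The proliferation marker MKI67 rose 1.27-fold (adjusted p = 0.0361). That call did not hold under 9 alternatives. It was lost with every probe set tested (limma adjusted p = 0.0709), with a further quantile normalization (0.0518) and with each line fitted alone (0.0857). It was also lost without KM-H2 4-OHT A, without KM-H2 control B and without any 1 of the L428 arrays. The log2 fold change was 0.28 without KM-H2 4-OHT A and 0.26 without KM-H2 control B, against 0.35 with all arrays.

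Of 22 genes of lysosomes and autophagy, 13 rose and 1 fell in KM-H2, and 8 did not pass (14 and 1 adjusted over the list alone). NPC2, a lysosomal cholesterol carrier, rose 6.17-fold, the protease gene CTSB 2.80-fold, WIPI1 2.48-fold and the autophagy receptor gene SQSTM1 2.40-fold. The list's median was 0.62 (camera adjusted p = 8.45e-07; adjusted p = 0.355 with an estimated correlation).

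Camera called no list of cell death genes in KM-H2; fry called the death-promoting genes upward (adjusted p = 0.00324) and the genes that oppose apoptosis downward (0.0394), and did not call the death receptors and caspases (0.247). Of 13 death-promoting members of the BCL2 family, 2 rose, 2 fell and 9 did not pass (2 and 2 adjusted over the list alone), with a median of −0.03, a mean of 0.21 and a camera adjusted p of 0.946 with direction up; the median was above 0 with each array centred on its median. BAK1 and BMF (2.43-fold) rose, and BAX fell 1.69-fold. Of 10 genes that oppose apoptosis, 4 fell, 1 rose and 5 did not pass (4 and 1 adjusted over the list alone; camera adjusted p = 0.0949). Without KM-H2 4-OHT A camera called this list (0.0149; range over all alternatives at the preset correlation 0.0149 to 0.264). BCL2A1 had the largest fall (log2 fold change −1.81, limma adjusted p = 0.000186), CFLAR fell 2.37-fold and BCL2 1.58-fold. Of 16 genes of death receptors and caspases, 3 rose, 4 fell and 9 did not pass (4 and 4 adjusted over the list alone), with a median of −0.06, a mean of 0.13 and a camera adjusted p of 0.991 with direction up. The initiator caspase gene CASP9 rose 7.58-fold and its partner APAF1 2.89-fold, and FAS fell 1.93-fold and CASP6 1.82-fold. Of 14 genes listed beforehand as reported KLF4 targets, 4 rose, 1 fell and 9 did not pass (4 and 2 adjusted over the list alone; camera adjusted p = 0.423, fry 0.00255 upward). Among them the cell cycle inhibitor gene CDKN1A rose 1.46-fold (adjusted p = 0.00705), a call that was lost without KM-H2 control B (log2 fold change 0.44, adjusted p = 0.0682; range over all alternatives 0.00433 to 0.0682), and the cyclin gene CCND2 rose 1.44-fold. Of 22 members of the KLF and SP family of transcription factors, 7 rose, 2 fell and 13 did not pass (7 and 2 adjusted over the list alone; camera adjusted p = 0.0508). The list passed with the replicate letter as a block across both lines (0.044), with cyclic loess (0.0481), without KM-H2 control A (0.0435), without KM-H2 4-OHT A (0.0358) and without KM-H2 control B (0.0411), over a range of 0.0358 to 0.0803 in all alternatives at the preset correlation. By fry it was called upward (0.00011). KLF3 rose 5.43-fold, KLF10 5.33-fold, KLF12 4.92-fold and KLF13 3.76-fold.

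Markers of the Hodgkin and B-cell lineages moved in both directions in KM-H2. Of 25 genes characteristic of Hodgkin cells, 6 rose, 7 fell and 12 did not pass (8 and 10 adjusted over the list alone; camera adjusted p = 0.896). TNFRSF8, which encodes CD30, the diagnostic surface marker of these cells, fell 1.42-fold, and the transcription factor gene MSC fell 3.16-fold, while PDCD1LG2, an inhibitory ligand of T cells, rose 2.71-fold and NOTCH1 2.21-fold. Of 26 B-cell genes, 4 rose, 3 fell and 19 did not pass (4 and 4 adjusted over the list alone; camera adjusted p = 0.946 with direction up, against a mean of −0.02 and a median of −0.02 that was above 0 with centred arrays and with a further quantile normalization). The transcription factor gene SPIB rose 5.15-fold and the kinase gene LYN 2.16-fold, the complement receptor gene CR2 fell 5.31-fold and CD22 3.12-fold, and PAX5 stood at 5.38 with vehicle and 5.34 with 4-OHT (adjusted p = 0.899). PRDM1, a regulator of plasma cell differentiation, stood at 5.30 and 5.52 (adjusted p = 0.448), except that it passed without KM-H2 4-OHT B (log2 fold change 0.55, adjusted p = 0.0106; range over all alternatives 0.0106 to 0.758). Of 15 JAK-STAT target genes, 7 fell, 4 rose and 4 did not pass (7 and 5 adjusted over the list alone; camera adjusted p = 0.336, fry 0.00324 downward), with PIM2 down 7.22-fold, IL2RA down 2.87-fold and SOCS1 down 2.65-fold.

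Camera called none of the lists of markers of other cell types in KM-H2, while fry called the stromal and endothelial list upward (adjusted p = 0.0162). Of 23 T and NK cell genes, 4 rose and 19 did not pass (camera adjusted p = 0.492), the largest being the T-cell receptor component CD3G, which rose 5.95-fold. Of 22 myeloid genes 2 rose and 20 did not pass (0.492), of 16 stromal and endothelial genes 2 rose, 1 fell and 13 did not pass (0.492), and none of 11 erythroid and megakaryocyte genes passed limma's test (3 had an unadjusted p under 0.05), nor did the list by camera (0.799) or fry (0.635).

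The second comparison asked the same of L428 cells. EMP1, a membrane protein gene, rose from 3.18 to 9.76 (log2 fold change 6.58 ± 0.11 SE, n = 2 arrays per group, adjusted p = 5.72e-10). Its vehicle level lay within the range of the dimmest of 5 equal classes of probe sets (1.95 to 3.30), so the corresponding 95.5-fold is measured against a level not shown to be above background. The integrin gene ITGB7 rose 33.2-fold, from 5.18 to 10.24. BAK1 rose 5.38-fold, from 7.35 ± 0.13 to 9.78 ± 0.10 (mean ± SD, n = 2; adjusted p = 6.12e-07), the cell cycle inhibitor gene CDKN1A 3.25-fold, and MYC fell 1.99-fold (log2 fold change −0.99 ± 0.11 SE). All 22 measured genes of ribosome biogenesis fell, genes of cholesterol synthesis fell as a group by camera at its preset correlation, and lists of immediate early genes and of lysosomes and autophagy were called upward. None of these list calls held with an estimated correlation (adjusted p = 0.356 for ribosome biogenesis, 0.597 for cholesterol synthesis, 0.356 for immediate early genes and 0.525 for lysosomes and autophagy). In L428, 5946 probe sets passed the adjusted p of 0.05, 2311 upward and 3635 downward; 499 of the rises and 563 of the falls were at least 2-fold. They stood for 1943 genes that rose and 3216 that fell. Falls outnumbered rises most among bright probe sets: in the brightest of 5 equal classes of the tested probe sets 691 rose and 1467 fell, with a median log2 fold change of −0.161, and in the dimmest class 79 rose and 53 fell.

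**Figure D1:**
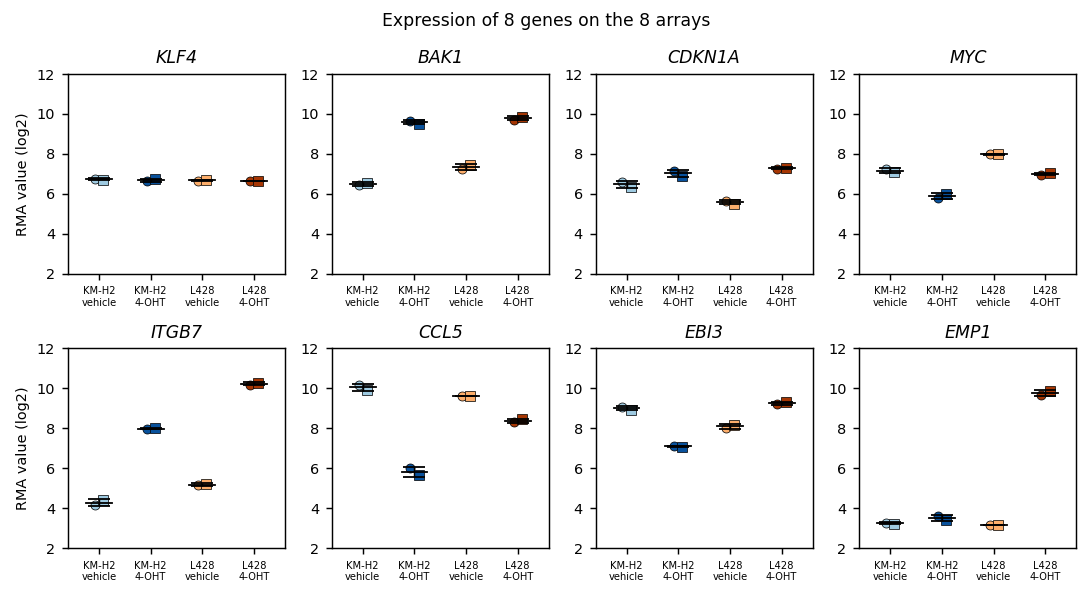
Expression of 8 genes on the 8 arrays, on the RMA log2 scale; circles are replicate A, squares replicate B, bars the mean of a group and error bars its SD (n = 2). KLF4 stayed between 6.65 and 6.73 in all group means, BAK1 rose in both lines, EMP1 rose from 3.18 to 9.76 in L428, and EBI3 fell to 7.09 in KM-H2 and rose from 8.09 to 9.26 in L428.

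After EMP1 and ITGB7, the strongest rises in L428 were S100A16 (30.8-fold), the prostacyclin receptor gene PTGIR (12.8-fold), the receptor tyrosine kinase gene TYRO3 (11.6-fold), NIBAN2 (9.22-fold), the calcium pump genes ATP2B4 (8.60-fold) and ATP2A3 (7.55-fold), the water channel gene AQP3 (8.49-fold), CD52 (7.96-fold), the calcium channel subunit gene CACNB3 (7.54-fold) and ATOSB (7.43-fold). The strongest falls were FRG2C (12.5-fold), CXCL10 (7.62-fold), the mitophagy gene BNIP3 (7.42-fold), the phosphatase gene PTPRR (6.61-fold), the acetylcholine receptor subunit gene CHRNA6 (6.52-fold), the chemokine receptor gene CCR4 (6.24-fold, from 10.17 to 7.53), TMTC1 (5.76-fold), the anti-apoptotic BCL2L10 (5.68-fold), the tetraspanin gene TSPAN33 (5.68-fold), ENTREP1 (5.39-fold), the actin-binding PFN2 (5.31-fold) and DUSP6, a phosphatase that acts on ERK (5.22-fold). The SE of the log2 fold changes of these genes lay between 0.10 and 0.26. FRG2C belongs to a family of near-identical copies, so its probes may read several of them.

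The 22 genes of ribosome biogenesis and MYC targets that fell in L428 also numbered 22 adjusted over the list alone. The spermidine synthase gene SRM fell 3.65-fold, CAD 3.26-fold, the RNA polymerase I subunit gene POLR1B 2.94-fold and MYBBP1A 2.55-fold. The median was −0.93 (camera adjusted p = 1.14e-15; adjusted p = 0.356 with an estimated correlation), against a median of −0.16 and a lower limit (the 2.5th percentile) of −0.35 in random lists of the same size and brightness. Of 26 genes of cytosolic ribosomal proteins, 14 fell and 12 did not pass (21 adjusted over the list alone), and RPL10A fell 1.73-fold, RPL35 1.57-fold and RPL13 1.54-fold. Their median was −0.30 (camera adjusted p = 6.99e-06; adjusted p = 0.415 with an estimated correlation), which lay at the 2.62th percentile of matched random lists, within their central 95%. It was −0.17 with a further quantile normalization and −0.14 with cyclic loess. Of 25 genes of cholesterol synthesis, 14 fell, 3 rose and 8 did not pass (15 and 3 adjusted over the list alone), with a median of −0.39 (camera adjusted p = 0.0012; adjusted p = 0.597 with an estimated correlation). DHCR7, the last step of the pathway, fell 4.23-fold, ACAT2 2.94-fold and the mevalonate kinase gene MVK 2.31-fold, whereas LSS, the lanosterol synthase gene, rose 2.24-fold and SREBF1, a regulator of lipid synthesis genes, 2.19-fold. HMGCS1 stood at 9.18 with vehicle and 9.12 with 4-OHT (adjusted p = 0.829). In KM-H2 the same list divided, with 8 members up, 9 down and 8 not past the test (10 and 9 adjusted over the list alone); its median was −0.16, its mean 0.06 and its camera direction up (adjusted p = 0.946). There FADS2 rose 6.23-fold and LSS 5.02-fold, MVK fell 3.20-fold, and HMGCS1 fell 1.53-fold (adjusted p = 0.0163), a call lost without KM-H2 control A (0.141), without KM-H2 4-OHT B (log2 fold change −0.39 against −0.61, adjusted p = 0.111) and with every probe set of the array tested (0.0551), over a range of 0.00324 to 0.141 in all alternatives.

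Of 22 immediate early genes, 14 rose, 2 fell and 6 did not pass in L428 (14 and 2 adjusted over the list alone). The AP-1 genes FOSL2 and JUNB rose 4.18-fold and 3.20-fold and IER3 rose 3.36-fold. The median was 0.54 (camera adjusted p = 6.99e-06; adjusted p = 0.356 with an estimated correlation). In KM-H2 6 of them rose, 4 fell and 12 did not pass (9 and 5 adjusted over the list alone; camera adjusted p = 0.786). Of 22 genes of lysosomes and autophagy, 11 rose, 5 fell and 6 did not pass in L428 (11 and 5 adjusted over the list alone), with SQSTM1 up 2.67-fold, the regulator of lysosomal genes TFEB up 2.21-fold, MAP1LC3B up 1.99-fold and UVRAG down 1.99-fold. The median was 0.40 (camera adjusted p = 0.0368; adjusted p = 0.525 with an estimated correlation). Of 27 genes of epithelia and keratins, 5 rose and 22 did not pass (3 adjusted over the list alone), with KRT8 up 3.50-fold and SFN up 3.06-fold. Their median was 0.17 (camera adjusted p = 0.019; adjusted p = 0.415 with an estimated correlation), and the call was lost with a further quantile normalization (0.0631) and with cyclic loess (0.065), over a range of 0.00797 to 0.065 in all alternatives at the preset correlation. The median was then 0.11 and 0.09. Of 35 genes of the G1/S transition and replication, 13 fell, 3 rose and 19 did not pass (15 and 3 adjusted over the list alone), with MCM10 down 2.11-fold, GINS2 down 1.99-fold, MCM2 down 1.74-fold and E2F2 up 2.99-fold. Their median was −0.21 (camera adjusted p = 0.0348; adjusted p = 0.59 with an estimated correlation), at the 27.7th percentile of random lists matched on brightness. This call was lost without L428 4-OHT A (0.0884), without L428 control B (0.0813), with dim probe sets left out (0.0565), with a further quantile normalization (0.271) and with cyclic loess (0.571), over a range of 0.02 to 0.571 in all alternatives at the preset correlation. The median was −0.11 without L428 4-OHT A, −0.11 with the further quantile normalization and −0.09 with cyclic loess.

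In L428 the NF-κB target genes divided: 13 rose, 7 fell and 9 of 29 did not pass (13 and 7 adjusted over the list alone; camera adjusted p = 0.223, fry 0.0212 upward). CXCL10 fell 7.62-fold and the co-stimulatory ligand gene CD86 3.68-fold, and TNFAIP2 rose 4.63-fold and IER3 3.36-fold. Of 9 MHC class II genes, 5 fell and 4 did not pass (5 adjusted over the list alone; camera adjusted p = 0.0575). The list passed with the replicate block within each line (0.0406), without KM-H2 control A or KM-H2 control B (0.046), without L428 control A (0.0465) and without L428 4-OHT B (0.0485), over a range of 0.0406 to 0.123 in all alternatives at the preset correlation. Among its members HLA-DOA fell 1.91-fold, HLA-DMA 1.63-fold and HLA-DPA1 1.46-fold. BAK1 and BIK rose among the death-promoting BCL2 genes, with 11 of 13 not past the test (2 adjusted over the list alone; camera adjusted p = 0.286, fry 0.00223 upward). The call of BIK (adjusted p = 0.0287) was lost without L428 control A (0.072), without L428 4-OHT A (0.167), without L428 control B (0.153), with every probe set tested (0.053), with a further quantile normalization (0.075) and with cyclic loess (0.116), over a range of 0.0212 to 0.167 in all alternatives. Of 10 genes that oppose apoptosis 2 fell, 1 rose and 7 did not pass (2 and 1 adjusted over the list alone; camera adjusted p = 0.286, fry 0.0277 downward): BCL2L10 fell 5.68-fold and BCL2L1 1.87-fold, and BCL2 stood at 6.31 with vehicle and 6.10 with 4-OHT (adjusted p = 0.169). BCL2A1, which fell in KM-H2, rose in L428 (log2 fold change 0.69). That call was lost with every probe set tested (limma adjusted p = 0.112), with a further quantile normalization (0.0901), with centred arrays (0.053) and with cyclic loess (0.131). It was also lost when single arrays were left out. Of 16 genes of death receptors and caspases 4 rose, 2 fell and 10 did not pass (4 and 2 adjusted over the list alone; camera adjusted p = 0.655), with APAF1 up 2.29-fold and CASP6 down 2.61-fold. Of the 14 genes listed as reported KLF4 targets 4 rose, 2 fell and 8 did not pass (4 and 2 adjusted over the list alone; camera adjusted p = 0.239, fry 0.00223 upward), among them CCND2, up 1.60-fold, and ODC1, down 1.58-fold. Of 22 KLF and SP genes 7 rose, 3 fell and 12 did not pass (8 and 3 adjusted over the list alone; camera adjusted p = 0.0575), with KLF10 up 4.45-fold, KLF3 up 2.25-fold and KLF6 down 3.18-fold. That list passed with a further quantile normalization (0.0454), with cyclic loess (0.0441) and without L428 control A (0.049), over a range of 0.0441 to 0.113 in all alternatives at the preset correlation. By fry it was called upward (0.000351).

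Of 25 genes characteristic of Hodgkin cells, 8 rose, 10 fell and 7 did not pass in L428 (8 and 11 adjusted over the list alone; camera adjusted p = 0.493), with MSC down 4.21-fold and TNFRSF8 down 1.63-fold. Of 26 B-cell genes 3 fell and 23 did not pass (3 adjusted over the list alone; camera adjusted p = 0.66), and PAX5 stood at 5.06 and 5.09 (adjusted p = 0.892). PRDM1 fell 1.58-fold (adjusted p = 0.0159). That call was lost without L428 control A (0.0783), without L428 control B (0.0744), without L428 4-OHT A (0.0512), without L428 4-OHT B (0.0893) and with every probe set tested (0.0523), over a range of 0.000799 to 0.0893 in all alternatives. Of 35 genes of mitosis 7 rose, 2 fell and 26 did not pass (7 and 2 adjusted over the list alone); their median was −0.02, their mean 0.05 and the camera direction up (adjusted p = 0.655), and the median was above 0 with a further quantile normalization and with cyclic loess. With cyclic loess the list passed upward (0.0233; range over all alternatives at the preset correlation 0.0233 to 0.741). MKI67 rose 1.44-fold (adjusted p = 0.0038). Of 23 T and NK cell genes 4 rose and 19 did not pass (camera adjusted p = 0.0575). The list passed without KM-H2 4-OHT A or KM-H2 4-OHT B (0.0487; range over all alternatives at the preset correlation 0.0487 to 0.141). Of 22 myeloid genes 3 rose, 1 fell and 18 did not pass (0.239), and of 16 stromal and endothelial genes 1 rose, 2 fell and 13 did not pass (0.992, with a median of 0.05, below 0 with a further quantile normalization and with cyclic loess, and a mean of −0.02). Fry called the T and NK cell list (0.018) and the myeloid list (0.0286) upward and not the stromal and endothelial one (0.933). None of 11 erythroid and megakaryocyte genes passed limma's test (2 had an unadjusted p under 0.05), and the list passed neither camera (0.223) nor fry (0.125). In the alternatives GATA1 passed without KM-H2 4-OHT A or KM-H2 4-OHT B (0.0436), with each line fitted alone (0.0425) and with array weights (0.0395; range over all alternatives 0.0395 to 0.283). EPOR passed without L428 control B (0.0378), with dim probe sets left out (0.0488) and with array weights (0.0416; range 0.0378 to 0.323).

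The third question was how far the lines responded alike. Averaged over both lines, ITGB7 rose by 4.37 on the log2 scale, S100A16 by 4.15 and CD52 by 3.63, and CXCL10 fell by 3.27 and the transcription factor subunit gene TAF4B by 2.12. BAK1, APAF1, KLF10, SQSTM1, VEGFA and FOSL2 rose in both lines, and MYC, CXCL10, CD86, MSC, CAD and MVK fell in both. VEGFA, a growth factor for blood vessels, rose 2.84-fold in KM-H2 and 2.91-fold in L428. The test of the difference between the lines was not passed by CXCL10 (adjusted p = 0.254), MYC (0.241), KLF10 (0.234) or ATP2B4 (0.811). Over the mean of both lines 6892 probe sets passed, 2854 upward and 4038 downward. Taken line by line, 1004 probe sets rose in both lines, where 264.8 would do so if the calls were independent, and 1406 fell in both, against 451.8 (Fisher's exact test, 1e-300 or less in each direction, the smallest p written). Of 2670 probe sets called in both lines, 90.3% moved in the same direction. Across all probe sets the log2 fold changes of the lines correlated with Pearson's r = 0.479 and Spearman's rho = 0.349. The lines share no array, and with each line fitted alone the shared calls numbered 2250.

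Opposite responses were fewer than independent calls would give: 168 probe sets rose in KM-H2 and fell in L428, against 417 for independent calls (Fisher's exact test, p = 9.11e-55), and 92 did the reverse, against 287 (p = 6.92e-49). All 260 passed the test of the difference, which calls in opposite directions make all but certain. The largest of them were in SLFN5, which fell 2.74-fold in KM-H2 and rose 3.75-fold in L428, EBI3, a cytokine subunit gene, which fell 3.74-fold and rose 2.25-fold, and OPN3, which rose 4.21-fold and fell 1.94-fold. ODC1 rose 1.63-fold in KM-H2 and fell 1.58-fold in L428.

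**Figure D2:**
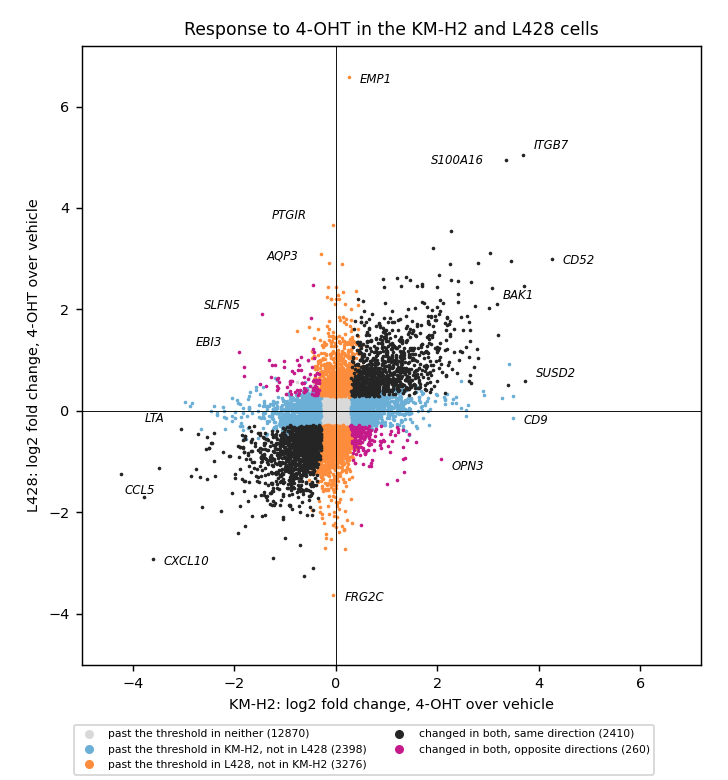
Log2 fold change (4-OHT over vehicle) of the 21214 probe sets tested, KM-H2 on the horizontal and L428 on the vertical axis, each point a probe set coloured by whether it passed an adjusted p of 0.05. Of the probe sets, 2410 changed in both lines in the same direction, 260 in opposite directions, 2398 passed in KM-H2 and not in L428, and 3276 in L428 and not in KM-H2.

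The fourth comparison tested the response in L428 minus that in KM-H2 for each probe set. EMP1 responded more in L428 (difference 6.32 ± 0.15 SE, adjusted p = 2.85e-08); it stood at 3.24 and 3.50 in KM-H2 with vehicle and 4-OHT, in or near the dimmest class of probe sets, so the difference is a rough size. PTGIR (difference 3.73), AQP3 (3.38) and ATP2A3 (3.04) also rose in L428, with no call in KM-H2. CXCL12 (3.15) fell in KM-H2 with no call in L428, and CCL5 (2.99) fell in both lines and further in KM-H2. CD9 (−3.63), ATL1 (−3.21), SUSD2 (−3.14), GPR155 (−3.02) and ATP1B1 (−2.88) rose in KM-H2 with a lower response in L428, where CD9, ATL1 and GPR155 were not called, and FRG2C (−3.59) and PTPRR (−2.91) fell in L428. CDKN1A rose further in L428 (difference 1.15 ± 0.17 SE, adjusted p = 0.00164) and BAK1 less far (−0.64 ± 0.16, adjusted p = 0.0209). CASP9 rose in KM-H2 with a lower response in L428 (−2.61, adjusted p = 0.000167). In all, 3571 probe sets passed, 1389 with a higher and 2182 with a lower response in L428; with each array centred on its median the numbers were 1061 and 2841. Without L428 control A 2266 passed and without L428 control B 2364.

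As a list, the 29 NF-κB target genes responded differently: 20 were higher in L428 relative to KM-H2, 1 lower and 8 did not pass (21 and 1 adjusted over the list alone; median difference 0.90, camera adjusted p = 6.22e-15; adjusted p = 0.334 with an estimated correlation). LTA (difference 2.69), CCL5 (2.99) and CD40 (1.85) were among them. Of 9 MHC class II genes 5 were higher and 4 did not pass (7 adjusted over the list alone; median 0.63, camera adjusted p = 2.97e-05; adjusted p = 0.452 with an estimated correlation), with HLA-DPB1 at 2.26. Of 22 immediate early genes 11 were higher, 4 lower and 7 did not pass (14 and 4 adjusted over the list alone; median 0.60, camera adjusted p = 0.000227; adjusted p = 0.386 with an estimated correlation), with JUNB at 1.39. Of 25 genes of cholesterol synthesis 12 were lower and 13 did not pass (14 lower and 1 higher adjusted over the list alone; median −0.55, camera adjusted p = 0.000227; adjusted p = 0.622 with an estimated correlation), with FADS2 at −1.93 and LSS at −1.16. Of 7 MHC class I genes 3 were higher and 4 did not pass (3 adjusted over the list alone; median 0.35, camera adjusted p = 0.0247; adjusted p = 0.632 with an estimated correlation). Of 26 interferon-responsive genes 7 were higher, 2 lower and 17 did not pass (10 and 3 adjusted over the list alone; median 0.44, camera adjusted p = 0.0244; adjusted p = 0.622 with an estimated correlation). Both of these calls were lost without KM-H2 control A (0.0839 and 0.0629), without KM-H2 4-OHT B (0.123 and 0.0776) and without L428 control A (0.0692 and 0.0843), over ranges of 0.0025 to 0.123 and 0.00463 to 0.0843 in all alternatives at the preset correlation. Without L428 control A the median of the interferon list was 0.29.

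Of 22 genes of lysosomes and autophagy 8 responded less in L428 and 14 did not pass (8, and 1 in the other direction, adjusted over the list alone; median difference −0.30, camera adjusted p = 0.00834; adjusted p = 0.452 with an estimated correlation), with NPC2 at −2.04. Of 22 genes of ribosome biogenesis 7 responded further downward in L428 and 15 did not pass (12, and 1 in the other direction, adjusted over the list alone; −0.40, camera adjusted p = 0.00158; adjusted p = 0.593 with an estimated correlation), with SRM at −1.14. Of 26 ribosomal protein genes 2 did so and 24 did not pass (1 adjusted over the list alone; −0.30, camera adjusted p = 0.000937; adjusted p = 0.474 with an estimated correlation). These calls were lost with a further quantile normalization (0.0553, 0.0598 and 0.112) and with cyclic loess (0.0523, 0.064 and 0.24), over ranges of 0.0029 to 0.0553, 0.000418 to 0.064 and 0.000585 to 0.24 in all alternatives at the preset correlation. Their medians were −0.18, −0.25 and −0.13 with the former and −0.24, −0.28 and −0.15 with the latter.

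**Figure D3:**
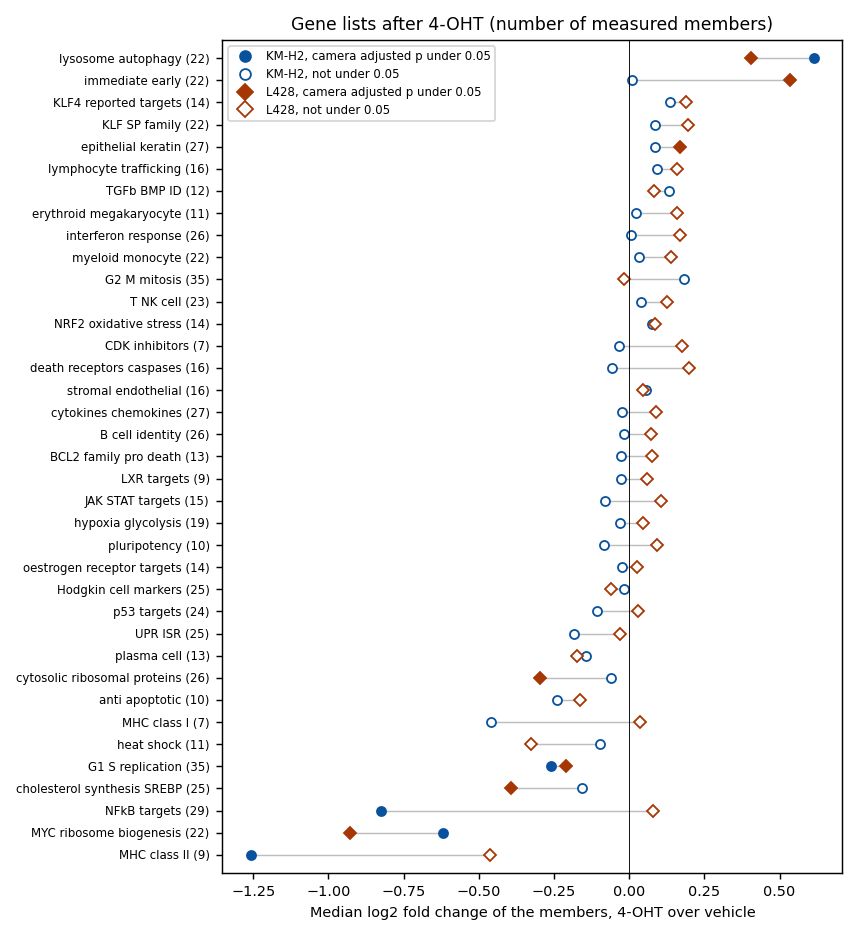
Median log2 fold change (4-OHT over vehicle, horizontal axis) of the measured members of each of the 37 gene lists, circles for KM-H2 and diamonds for L428, filled where camera with a preset correlation gave an adjusted p under 0.05. The NF-κB list lay at −0.82 in KM-H2 and 0.08 in L428, ribosome biogenesis at −0.62 and −0.93 and lysosome and autophagy genes at 0.62 and 0.40.

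The fifth comparison set the vehicle-treated lines side by side, L428 against KM-H2, to show the levels from which the responses began. L428 had more of SH2D1B, a signalling adaptor of lymphocytes (125-fold, log2 difference 6.97 ± 0.14 SE, n = 2 arrays per group), the complement regulator gene CFI (97.9-fold), the chemokine gene CCL1 (75.5-fold) and PHGDH, the first enzyme of serine synthesis (61.1-fold). It had less of DHRS2 (105-fold, log2 difference −6.72 ± 0.16), the cancer-testis gene MAGEA4 (86.8-fold) and CR2 (74.1-fold). The KM-H2 levels of SH2D1B (2.64) and CFI (2.81) and the L428 level of CR2 (3.24) lay among the dimmest probe sets, so these folds are rough sizes. BAK1 began at 6.51 in KM-H2 and 7.35 in L428, MYC at 7.17 and 7.99, and CDKN1A at 6.47 and 5.58. Altogether 8279 probe sets differed, 4170 of them higher in L428 and 4109 lower. Genes of mitosis were higher in L428 (25 of 35 higher, 3 lower, 7 not past the test; 26 and 3 adjusted over the list alone; median 0.64, camera adjusted p = 2.3e-07; adjusted p = 0.564 with an estimated correlation), as were interferon-responsive genes (16 of 26 higher, 3 lower, 7 not past the test; 18 and 3 adjusted over the list alone; median 1.20, camera adjusted p = 5.72e-06; adjusted p = 0.571 with an estimated correlation). The same held for genes of the unfolded protein and integrated stress responses (16 of 25 higher, 5 lower, 4 not past the test, and likewise adjusted over the list alone; camera adjusted p = 0.00366; adjusted p = 0.571 with an estimated correlation) and for plasma cell genes (6 of 13 higher, 1 lower, 6 not past the test, and likewise adjusted over the list alone; camera adjusted p = 0.018; adjusted p = 0.564 with an estimated correlation). Of 25 genes characteristic of Hodgkin cells 15 were higher, 7 lower and 3 did not pass (15 and 8 adjusted over the list alone; camera adjusted p = 0.0404; adjusted p = 0.765 with an estimated correlation). This call was lost without KM-H2 control B (0.0639), without KM-H2 4-OHT A or KM-H2 4-OHT B (0.051), without L428 4-OHT A or L428 4-OHT B (0.0504) with each array centred on its median (0.0729) and in 4 other settings, over a range of 0.0177 to 0.0729 in all alternatives at the preset correlation.

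Camera with its preset correlation called 5 of 37 lists in KM-H2, 7 in L428, 9 over the mean of both lines, 9 in the difference between the lines and 5 between the vehicle-treated lines. With the correlation estimated from these arrays camera called 0 of them in any of the 5 comparisons, with 5, 3, 4, 2 and 2 lists at an unadjusted p under 0.05. Fry, whose p-value tests whether a list's genes moved on balance in one direction and does not compare the list with other genes, called 20, 19, 29, 15 and 25.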

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

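The test on vehicle levels, the test for an offset of the arrays and the use of cyclic loess were chosen only after the result was seen. For the other tests the expected outcomes were set before their own results were seen. The patterns that the brightness-matched lists examine, such as the fall of ribosomal protein genes in L428, had been seen in these data first. The results below are those in which the response to 4-OHT differed between the lines by limma's test of the difference or camera's test on it, and those in probe sets left out of the comparisons.

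NF-κB target genes and MHC class II genes responded lower in KM-H2, where both lists fell, than in L428, where the NF-κB list divided, with median differences (L428 minus KM-H2) of 0.90 and 0.63; these list calls did not hold with an estimated correlation (adjusted p = 0.334 and 0.452). A vehicle level too low in L428 to fall further is argued against by the 28 of 38 measured members, whatever their response, that began in L428 within 0.5 log2 units of their KM-H2 level or above it: their median difference was 1.04 (quartiles 0.32 and 1.32), with medians of −0.01 in L428 and −0.83 in KM-H2. After cyclic loess the median difference of the 27 members that fell in KM-H2 was 106% of its value (1.26 against 1.19). These 27 were picked by their fall in the same data, which enters the difference. Over 5 classes of brightness the median log2 fold change lay between −0.048 and 0.0045 in KM-H2 and between −0.161 and 0.099 in L428. So cyclic loess could change the difference little, and the small size of these medians argues against a brightness-dependent shift as its source. For the 10 of the 38 members that began further below their KM-H2 level, with a median difference of 0.83, a low starting level stays open. A difference between the lines themselves stays open and was not tested.

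In L428 more probe sets fell than rose, among them genes of ribosome biogenesis and of ribosomal proteins (adjusted p = 0.356 and 0.415 with an estimated correlation), and the quartiles of the treated arrays lay closer together. A narrower range of values on those arrays is argued against as the whole source of the excess, since the share that rose was 40.0% after cyclic loess and 43.8% after a further quantile normalization, and a downward offset is argued against by the medians of the treated arrays (4.51 and 4.49), above those of the vehicle arrays (4.42 and 4.43), and by the median log2 fold change of all tested probe sets, 0.038. For ribosome biogenesis the list's median of −0.928 lay below all 10000 random lists matched on brightness, whose median was −0.16. That argues against a narrower range as the whole source of the fall. The random lists ignore correlation between members, estimated at 0.239 for this list, so their spread is too small for it. For the ribosomal protein genes the median of −0.297 lay within the central 95% of such lists (2.5th percentile −0.30), so the narrower range may account for their fall. A real loss of abundant transcripts in L428 stays open, since RMA levels show only proportions of each RNA sample.

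Genes of cholesterol synthesis fell in L428, with a median of −0.394 at the 0.52th percentile of random lists matched on brightness; the list's call did not hold with an estimated correlation (adjusted p = 0.597). That position lay below the 2.5th percentile of those lists (−0.326), whose median was −0.12. The random lists were drawn without regard to correlation between genes, and the estimated correlation of this list was 0.433. Their spread is thus too small for it. Their percentiles therefore cannot decide whether the narrower range of the treated arrays accounts for the fall. Actions of 4-OHT itself, and those of the fusion, stay open, since no cells without the fusion were treated.

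The response differed between the lines for 3571 probe sets. It was higher in L428 for EMP1 (6.32), PTGIR (3.73), AQP3 (3.38), SLFN5 (3.36), CXCL12 (3.15), EBI3 (3.07), ATP2A3 (3.04) and CCL5 (2.99), given as differences in log2 fold change. It was lower in L428 for CD9 (−3.63), FRG2C (−3.59), ATL1 (−3.21), SUSD2 (−3.14), OPN3 (−3.03), GPR155 (−3.02), PTPRR (−2.91) and ATP1B1 (−2.88). The median difference was 0.35 for MHC class I genes, 0.44 for interferon-responsive genes, 0.60 for immediate early genes, −0.55 for cholesterol synthesis, −0.30 for lysosome and autophagy genes, −0.40 for ribosome biogenesis and −0.30 for ribosomal protein genes. None of these list calls held with an estimated correlation (adjusted p = 0.632, 0.622, 0.386, 0.622, 0.452, 0.593 and 0.474). The last 3 were also lost with a further quantile normalization (medians −0.18, −0.25 and −0.13; adjusted p = 0.0553, 0.0598 and 0.112) and with cyclic loess (0.0523, 0.064 and 0.24). The call of the MHC class I list was lost without KM-H2 control A (0.0839), KM-H2 4-OHT B (0.123) or L428 control A (0.0692), and that of the interferon list without the same arrays (0.0629, 0.0776 and 0.0843), with a median of 0.29 without L428 control A. Without L428 control A the number of probe sets was 2266, and without L428 control B it was 2364.

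Of the 12083 probe sets without a gene symbol, 257 were higher after 4-OHT in KM-H2 and 426 lower, and 377 were higher in L428 and 627 lower.

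More probe sets changed over both lines with the real split of the arrays than with any other split that could be fitted. This cannot exclude chance, since the splits are few and all others mix treated and vehicle arrays. Mixing puts any treatment effect into the spread of those splits, which lowers their numbers. With the cell line as a term, 4530 probe sets passed for the real split of the 8 arrays into 4 treated and 4 control, the highest number in any of the other splits was 24, and 1 of 35 splits, the real one, gave as many; the split that separates the lines could not be fitted.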

How the results depend on the processing

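Cyclic loess was chosen after seeing the data; the other alternatives were planned. No result turned its direction past the threshold. With a fold change of at least 2 as a further condition, 1093 probe sets passed in KM-H2 and 1062 in L428, fewer because the condition is stricter. Camera with an estimated correlation called 0 of 74 list tests in the lines, against 12 with the preset one (fry called 20 of 37 in KM-H2 and 19 in L428). Its p-values were also higher where the estimated correlation lay close to or below the preset 0.01. Camera's unadjusted p was 0.042 against 0.00257 for the epithelial list in L428 (estimated correlation 0.0122). It was 0.0457 against 0.00921 for the KLF and SP list in KM-H2 (−0.0358). Correlation between members thus does not account for the higher p in these 2 lists. At an estimated correlation camera uses the 4 residual degrees of freedom, against about the number of genes at the preset one. Fewer degrees of freedom alone raise the p of a given statistic. The simulated noise was independent between genes. There the shifted list's camera adjusted p was 1.72e-48 at the preset and 0.00308 at the estimated correlation. A call lost at the estimated correlation therefore does not show that members were correlated. Leaving out 1 array gave 3652 to 4864 probe sets in KM-H2, 4144 to 6464 in L428, 5912 to 6911 over both lines, 2266 to 3756 in the difference between the lines, 6795 to 8585 between the vehicle-treated lines, 1810 to 2351 shared and 11 to 17 list calls, some above and some below the numbers with all arrays, and the cause was not tested. Of 5984 values of named genes under alternatives, 5762 kept their direction and side of the threshold, 214 fell short of it and 8 came to pass it; of 3108 values of lists, 2992 kept theirs, 69 fell short and 47 came to pass. A block on the replicate letter gave 5156 in KM-H2 and 6128 in L428 across both lines, and 5361 and 6472 within each line, where the vehicle comparison could not be fitted. Fitted alone, KM-H2 gave 4316 and L428 6419, against 5068 and 5946 with the spread shared over all groups. The KM-H2 4-OHT replicates differed most from each other. There 3.54% of probe sets differed by more than 0.5 on the log2 scale, against 1.37% to 1.82% in the other replicate pairs. In the simulated data limma recovered 2% of changes of 0.3 on the log2 scale. There 200 probe sets were changed and 136 called, against 5068 called in the real KM-H2 comparison, so the adjusted p was harder to pass. The 2% thus does not carry over to the real comparison, where PHGDH (log2 fold change 0.33) and RPL3 (−0.32) were called. Both of these calls were lost under several alternatives, and the part of dim signal was not tested.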

Other observations

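None of the tests in this part was chosen after the result was seen, and no hypothesis is added here; the lists below were fixed before the data were examined and none was called by camera in the comparison it is given for.

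Genes of glucose use and of the response to low oxygen moved in both directions. In KM-H2 6 of 19 rose, 5 fell and 8 did not pass (6 and 7 adjusted over the list alone), with a median of −0.03, a mean of 0.06 and a camera adjusted p of 0.946 with direction up, and fry called them upward (0.036); the median was above 0 with each array centred on its median. In L428 5 rose, 7 fell and 7 did not pass (7 and 7 adjusted over the list alone), with a median of 0.05, a mean of −0.01 and a camera adjusted p of 0.908 with direction up. The glucose transporter gene SLC2A1 rose 2.16-fold in KM-H2 and 3.04-fold in L428, and SLC2A3 rose 3.31-fold in L428. The mitophagy gene BNIP3, a usual target of the hypoxia response, fell 2.35-fold in KM-H2 and 7.42-fold in L428. Of 11 heat shock genes 4 fell and 1 rose in KM-H2 (camera adjusted p = 0.336), and 6 fell and 1 rose in L428 (0.138); fry called them downward in both lines (0.00827 and 0.00483). HSPA4L fell 2.77-fold in KM-H2 and 2.45-fold in L428, and HSPH1 fell 1.72-fold in L428, while the small heat shock protein gene HSPB1 rose 2.72-fold in L428.

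Of 24 p53 target genes 6 rose, 6 fell and 12 did not pass in KM-H2 (7 and 7 adjusted over the list alone), with a median of −0.11, a mean of 0.05 and a camera adjusted p of 0.946 with direction down. In L428 8 rose, 3 fell and 13 did not pass (8 and 4 adjusted over the list alone; camera adjusted p = 0.286). The ribonucleotide reductase subunit gene RRM2B rose 4.24-fold in KM-H2, SESN1 rose 2.89-fold in KM-H2 and 3.03-fold in L428, TP53I3 rose 1.88-fold in L428 and CCNG1 fell 2.47-fold in L428. Of 16 genes of lymphocyte traffic 3 rose, 2 fell and 11 did not pass in KM-H2 (camera adjusted p = 0.497), and 4 rose, 3 fell and 9 did not pass in L428 (0.286); fry called the list upward in both lines (0.000555 and 0.000229). ITGB7 belonged to this list, SELPLG, a ligand of selectins, rose 4.30-fold in L428, and GPR183, which guides B cells in lymphoid tissue, fell 4.65-fold in L428.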
